A study of Danio rerio with 28 samples.

How the data were processed

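Single cells were prepared from wild-type TLAB zebrafish embryos raised in their chorions and staged by eye, whose chorions and yolk were removed by hand before mechanical dissociation, and polyadenylated RNA was captured by Drop-seq, per the labels' protocols. The values are counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell, as the authors deposited them, with no normalization. The submitters' processing notes name bcl2fastq 2.17.1.14 and Bowtie2 2.2.1, with no role given for either. The genome build, the annotation and the rule by which barcodes were accepted as cells are not given in the sources used here. Each cell's stage, batch and library came from its column name, matched to the labels, and 0 columns of per-sample values were left unused. The table held 39505 cells, 23974 genes and 183752428 UMIs, and the shallowest cell had 678 UMIs and 493 genes. Gene names are in capitals as in the table, and 18985 of them (79.19%) matched a RefSeq gene table of assembly GRCz12tu, which was used for names only. Counts of near-identical copies cannot be told apart where the counting split their reads. No pair of replicate libraries agreed within sampling noise, judged over genes with at least 20 counts, so none was taken for 1 library deposited 2 times and each of the 28 counted as 1 sample, which does not show that they are independent. Precision follows depth, which ran from 546249 to 14897499 UMIs per library.

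For tests over all cells, UMIs were summed per library and fitted with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest), with TMM normalization, filterByExpr at its minimum count of 10 and minimum total of 15, and a Benjamini-Hochberg adjusted p under 0.05. The blastula trend was a slope per hour over 8 libraries of DS5 from high to shield (6 residual degrees of freedom). Gastrula contrasts came from stage means over 17 libraries of DS2 to DS4 (12 degrees of freedom). The contrast of 6-somite and bud came from a natural cubic spline of hours with 4 degrees of freedom plus batch over all 28 libraries (20 degrees of freedom). Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation beside it, and with fry. The 33 lists, of which 16 are pathways or processes and 17 are cell types, the tests, samples, covariates and most alternatives were fixed before the data were examined. The results of 1 list, the class of cells named from it and some genes named by rule are not used here, though counts of lists and classes include them. The names zp3, velo1, h2af1o, chrd, aen, rps27l, mttp, msxb, crestin, en1b, tbxtb, evx1, cdx1a and npas4l were not found in the table under these names, and the yolk syncytial layer and globin lists had too few tested genes for a result in the blastula and gastrula contrasts. Of these chrd, mttp and en1b are in the table as CHD, MTP and ENG1B, seen only afterwards, so the BMP, early zygotic, yolk syncytial layer and midbrain and hindbrain lists lack them.

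Genes were named by rule. For each comparison over all cells the rule took the 10 largest rises and 10 largest falls among genes past the test with at least 50 CPM in the higher group and the same direction in each batch, and the 3 members of each list with the smallest p. Within a class it took 3 each way. Genes named for a clone or locus were passed over, and within a class also the 50 genes that define its clusters, the last a choice made after seeing the data. Folds against a stage with 0 counts are lower bounds from a floor of 3 counts over the stage, and ratios with 1 to 3 counts carry an exact 95% counting interval. Shares of cells carry an exact (Clopper-Pearson) 95% interval where a stage had 1 library or was pooled, and the limit printed for a share of 0 is 3 cells of the total.

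Cells were clustered in 3 windows, high to shield, 50% epiboly to bud and the somite stages, on counts scaled to 10000 per cell and log-transformed, with 2000 variable genes, 30 principal components, a graph of 20 neighbours and Leiden clustering at resolution 1.0 (scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, Python 3.11.15, with matplotlib 3.10.9 for the plots). A cluster took a class name when at least 3 markers of that class, each found in at least 5% of its cells, were among its 50 leading genes by fold (pseudocount 20 CPM), when its 10 leading genes held no more markers of another class than of its own, and for notochord, placode and germ cells when NOTO or TA, DLX3B, DLX4B or DLX4A, or DDX4 was among them. Clustering left out 71 genes that differed over 4-fold between libraries of 1 stage (CPM plus 5). These rules replaced a first version, with at least 2 markers and no genes left out, after its clusters had been seen. Doublets were scored with scrublet in scanpy (expected rate 5%, 20 components, libraries of at least 100 cells). It called 156 of 39385 scored cells (0.395%). The share was 8.745% in high DS5 and 12.5% in oblong DS5b, and at most 1.339% in the other scored libraries. In most libraries the share thus lay far below the expected rate, for a reason that was not settled, and no cell was removed. Removal of the called cells, and of the 1967 cells with the highest 5% of scores, were alternatives. Cells with under 1000 UMIs, 190 in all, were kept in the main results.

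Shares of classes were correlated with hours by Pearson's r and Spearman's rho over 17 libraries, with 100000 permutations of hours within batch, two-sided, adjusted over 13 classes. Expression within a class was tested with edgeR on UMIs summed per library and class, where each library from 60% epiboly to bud had at least 20 cells. For the axial panels a cell needed 2 UMIs of a panel, each cell was also thinned to 2000 UMIs, and libraries were compared by an exact permutation test. Thinning left out 197 cells at 60%, 673 at 75%, 732 at 90% epiboly and 1704 at bud.

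The labels give the batch, and libraries of 1 batch deviated together from their stage means: the mean correlation of deviations was 0.216 over 38 pairs of the same batch (-0.0111 to 0.584, 29 above 0.1) and -0.104 over 77 pairs of different batches (3 above 0.1). The batch was therefore the block in the blocked fits. Other alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, cells of at least 1000 UMIs, each library left out in turn, the rank of the stage in place of hours, splines of 3 and 5 degrees of freedom, no batch term, resolutions 0.6 and 2.0, 20 components, and each batch left out. Alternatives chosen after seeing the data were libraries thinned to the lowest total of the gastrula set (1792698 UMIs), 1 library per stage and batch, bud without its DS2 libraries, the blastula without libraries under 100 cells, libraries from 60% epiboly on, all variable genes kept, the highest scrublet scores removed, axial classes only, the prechordal panel without GSC, and the endoderm, notochord and prechordal classes.

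Each fit was tested on simulated data with counts drawn from the real means and library sizes and 200 genes changed. In the blastula trend 73.63% of genes changed by 1 log2 and 97.85% of those changed by 2 were recovered over 8727 genes, with 2.47% of calls false. The values were 42.11%, 79.17% and 4.92% over 12026 genes for bud against 50% epiboly, and 3.57%, 36.96% and 5.13% over 14170 genes for 6-somite against bud. Within classes they were 37.63%, 73.96% and 2.75% over 5350 genes for anterior neural, 47%, 88.42% and 5.76% over 7051 for epidermal, 35.71%, 84.69% and 4.84% over 6861 for paraxial, 30.77%, 74.47% and 5.77% over 4458 for endoderm, 20.21%, 70.1% and 7.45% over 3975 for notochord, and 12.5%, 66.67% and 12.64% over 3609 for prechordal cells.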

Results

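Gene expression was measured in single cells of wild-type TLAB zebrafish embryos, a cross of 2 laboratory strains, at 12 stages from high stage (3.3 h after fertilization) to the 6-somite stage (12 h). The method was Drop-seq, in which each cell shares a droplet with a barcoded bead and each captured transcript is counted once through its unique molecular identifier (UMI). The table held 39505 cells in 28 libraries, with a median of 3798 UMIs and 1444 detected genes per cell. High, oblong, 30% epiboly and 6-somite had 2 libraries each, dome, shield and 3-somite had 1 each, 60%, 75% and 90% epiboly had 3 each, and 50% epiboly and bud had 4 each. Total counts per library ranged from 546249 UMIs in an oblong library to 14897499 in a bud library, and cells per library from 48 at high to 4759 at bud. The 11 libraries of high, oblong, dome, 30% epiboly, shield and both somite stages came from the batch DS5. The 17 libraries from 50% epiboly to bud, without shield, came from DS2, DS3 and DS4. Stage and batch are therefore confounded between these sets. Nothing in the labels says that replicate libraries came from separate clutches, so p-values measure only the spread between these samples, which may be technical. Counting intervals and floors cover counting error only.

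Which transcripts were lost and which appeared as the embryo passed from maternal to zygotic control was asked first, within DS5, from high to shield. Transcripts stored in the oocyte fell. BTG4, an adaptor for the clearance of maternal mRNA, fell from 530 ± 125 CPM (counts scaled to the total of a library, SD, n = 2 libraries) at high to 0.90 at shield. Its ratio was 540 with a counting interval of 184 to 2620 (edgeR adjusted p = 3.4e-05). BUC, the Bucky ball protein that assembles the Balbiani body, fell from 237 ± 51.3 to 1.5 CPM, with a slope of -2.67 ± 0.25 log2 per hour (SE, adjusted p = 3.0e-05). WEE2, an oocyte kinase, fell from 523 ± 90.3 to 11.1 CPM, with a slope of -1.68 ± 0.15 (adjusted p = 2.6e-05). Several regulators of the ventral and posterior margin rose from low levels. EVE1 had 0.23 CPM at high and 357 at shield, a ratio of 1018 with a counting interval of 182 to 40254 (adjusted p = 5.3e-04). CDX4, a posterior homeobox regulator of Hox genes, rose from 1.87 ± 0.64 to 533 CPM, by 3.76 ± 0.35 log2 per hour (adjusted p = 2.9e-05). TA, the zebrafish Brachyury, rose from 7.00 ± 5.88 to 603 CPM, by 3.59 ± 0.57 (adjusted p = 3.2e-04). SOX32, the regulator of endoderm, reached 138 CPM at shield from 0.23 at high, a ratio of 393 with a counting interval of 70.24 to 15568 (adjusted p = 3.4e-05).

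The other genes with the largest falls were CBX8B, TRIM35-29, YIPF1, FBXO32, LIPG, MKNK2A, SLBP2 and UVRAG, and those with the largest rises were ADD3B, HER7, STM, KRT92, ALCAMB, APOC1 and CRABP2B. MKNK2A fell from 443 to 1.80 CPM, STM rose from 43.5 ± 55.5 to 2384 CPM, and APOC1, an apolipoprotein, rose from 19.5 to 957 CPM. ADD3B, with 0 counts at high, was at least 354-fold higher at shield and KRT92, a keratin, at least 89.2-fold, both against a floor of 3 counts over the stage. The heat shock gene HSPB1 rose from 367 ± 257 to 15685 CPM, by 2.77 ± 0.36 log2 per hour (adjusted p = 9.9e-05). In all, 5139 of 9216 genes changed along the 8 libraries, 2413 higher and 2726 lower with time. With DESeq2 size factors in place of TMM the split was 2706 higher and 2495 lower, and the median slope of all genes moved by 0.07 log2 per hour.

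**Figure D1:**
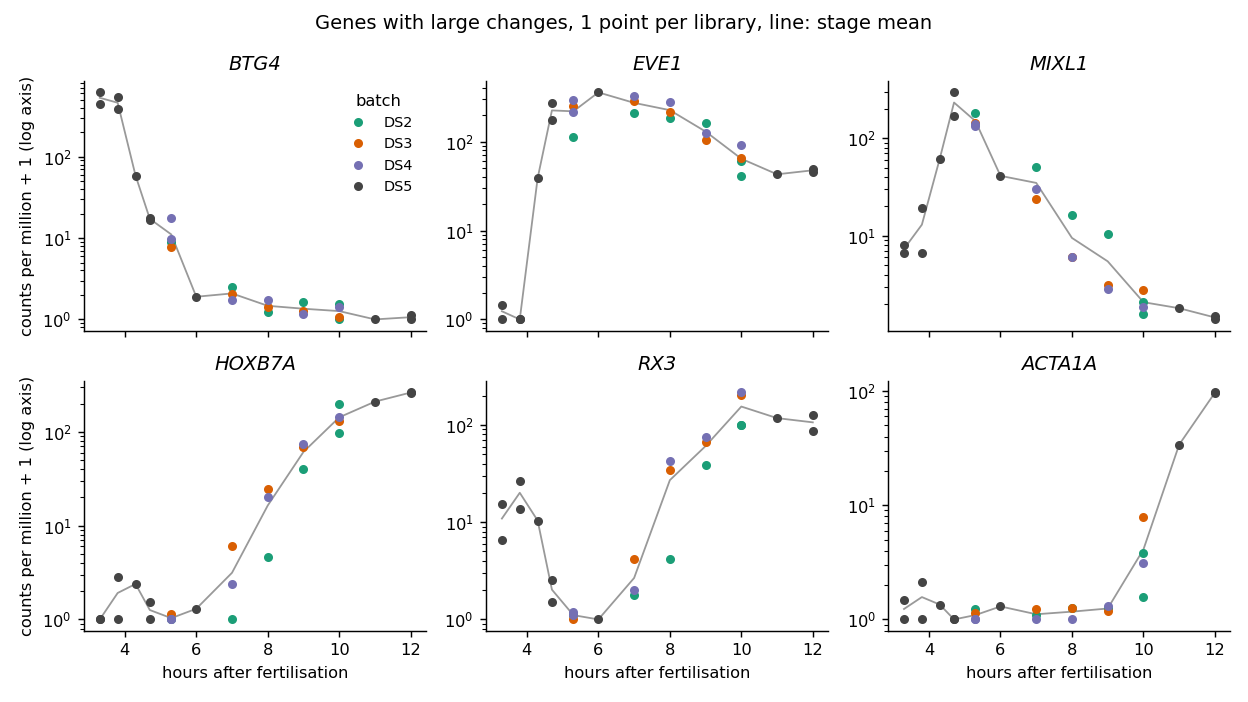
CPM plus 1 (log axis) of BTG4, EVE1, MIXL1, HOXB7A, RX3 and ACTA1A against hours after fertilization, with a point per library coloured by batch and a line through the stage means. BTG4 drops from 530 CPM at high to 0.90 at shield, EVE1 rises from 0.23 to 357 over the same stages, MIXL1 drops from 149 at 50% epiboly to 1.09 at bud, and ACTA1A reaches 95.8 at 6-somite.

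Of 27 gene lists fixed in advance 19 passed camera across the blastula, and with an estimated correlation 0 of these held (adjusted p = 0.161 to 0.378), where 5 lists had an unadjusted p under 0.05 and fry passed 22. In each pair below the value after the camera p is the one with an estimated correlation. Of 19 maternal oocyte genes 14 fell and 2 rose (camera adjusted p = 6.8e-05, and adjusted p = 0.161 with an estimated correlation). Among early zygotic genes 11 of 20 rose and 2 fell (adjusted p = 0.0031 and 0.181), with APOEB up from 298 ± 10.3 to 5432 CPM. All 79 ribosomal protein genes rose, with a median slope of 1.38 log2 per hour (adjusted p = 2.8e-31 and 0.162). So did 13 of 24 cell cycle genes, with 1 falling (adjusted p = 3.3e-04 and 0.162), among them CDK1 by 1.18 ± 0.11 log2 per hour. Up among signalling genes were 12 of 13 of the BMP list (adjusted p = 1.1e-05 and 0.162), and 8 of 11 of the Nodal list with 1 falling (adjusted p = 0.0057 and 0.256). The same held for 7 of 10 FGF genes with 1 falling (adjusted p = 0.0086 and 0.181), 6 of 8 Wnt genes (adjusted p = 3.9e-04 and 0.161) and 6 of 6 segmentation clock and Notch genes (adjusted p = 0.0050 and 0.162). Markers of later tissues rose in the endoderm (7 of 7, adjusted p = 7.9e-05 and 0.161), tailbud and margin (6 of 6, adjusted p = 1.8e-04 and 0.162) and epidermal (6 of 7, adjusted p = 0.0015 and 0.162) lists. They also rose in the plate border and crest (4 of 5, adjusted p = 0.0031 and 0.162), enveloping layer (5 of 7, adjusted p = 0.0137 and 0.378) and spinal cord (3 of 3, adjusted p = 0.0122 and 0.162) lists. Notochord (3 of 3, adjusted p = 0.0156 and 0.162) and paraxial genes (3 of 3, adjusted p = 0.0375 and 0.162) rose too. Of 10 immediate early and heat shock genes 5 rose and 1 fell (adjusted p = 0.036 and 0.162), and of 8 naive blastoderm genes 6 rose and 2 fell (adjusted p = 0.0134 and 0.219).

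Other lists did not pass camera. Of 10 germ cell genes 6 fell and 1 rose (adjusted p = 0.0805), H1M from 4107 to 332 CPM and DND1 with a slope of -0.90 ± 0.20 log2 per hour. Of 7 pluripotency factors 3 rose, among them POU5F3 from 466 ± 89.5 to 1877 CPM, and 3 fell, among them EOMESA from 82.2 to 1.2 CPM (adjusted p = 0.931). Of 5 retinoic acid genes 3 rose and 1 fell (adjusted p = 0.201), and of 5 prechordal genes 3 rose (adjusted p = 0.089). Of 3 blood genes 2 rose (adjusted p = 0.291). Of 4 anterior neural genes 1 rose and 3 fell (adjusted p = 0.783). Of 3 midbrain and hindbrain genes 1 rose and 1 fell (adjusted p = 0.813), where the median of 0.06 and mean of 0.26 were above 0 and the test pointed down. Adjusted over the list alone, 1 more gene passed in each of the Nodal, BMP, FGF, enveloping layer and prechordal lists, and the number passing was equal in every other list. Among the genes named by rule, the calls of OLIG4, NOTO, LMO2, MORC3B, RX3, GDF3, TFAP2A and FZD8B were each lost in at least 1 alternative. FZD8B (1.10 ± 0.23 log2 per hour) had an adjusted p = 0.832 without the shield library, in a range over its alternatives of an adjusted p = 1.1e-04 to 0.832. Dome and shield had 1 library each.

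The second question was what changed during gastrulation, from 50% epiboly to bud, where both stages were sequenced in DS2, DS3 and DS4. Among the genes with the largest rises, several of the body axis and of later tissues came up from near 0. HOXB7A, a Hox gene of the trunk, went from 0.03 to 142 CPM, a ratio of 4663 with a counting interval of 836 to 184223 (edgeR adjusted p = 7.0e-09). MEOX1, a homeobox gene of somites, went from 0 to 105 CPM, at least 1272-fold higher (adjusted p = 6.7e-10). RX3, the regulator of the eye field, rose from 0.11 ± 0.08 (SD, n = 4) to 154 ± 64.3 CPM (SD, n = 4), by 10.36 ± 0.87 log2 (SE, adjusted p = 5.1e-09). CTSLB, a protease of the hatching gland, rose from 0.10 ± 0.14 to 131 ± 82.1 CPM, by 10.13 ± 0.94 (adjusted p = 2.2e-08). MIXL1, a Nodal target of mesendoderm, fell by 6.69 ± 0.53 log2 from 149 ± 21.2 to 1.09 ± 0.53 CPM (adjusted p = 2.6e-09). CCNA1, the maternal cyclin A, fell by 7.99 ± 0.44 from 186 ± 50.6 to 0.63 ± 0.59 CPM (adjusted p = 5.4e-11), and NANOG fell by 5.67 ± 0.34 from 267 ± 77.6 to 5.24 ± 1.95 CPM (adjusted p = 1.5e-10).

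Other genes chosen by size were MYL10, HOXB1B, LSP1, TWIST1A, HOXC3A and HOXB9A, which rose, and MCTP2B, BLVRB, CLDND, OCLNA, MAP1LC3C, RHOQ and NNR, which fell. MYL10, a myosin light chain, had 0 counts at 50% epiboly and was at least 940-fold higher at bud. HOXB1B was higher by a ratio of 2312 (counting interval 791 to 11215). NNR, a zinc finger gene of the early embryo, fell from 1424 ± 212 to 14.1 ± 8.23 CPM. Across the genome 7941 of 12552 genes changed over 17 libraries, 4141 higher and 3800 lower. With DESeq2 size factors the split was 3770 higher and 4163 lower and the median of all genes moved by -0.11 log2, so the log2 values above stand relative to the TMM scale, on which the median was 0.06. The call of each gene named by rule in this comparison held in every alternative run but for GATA6. At -0.58 ± 0.31 log2 (adjusted p = 0.110) it passed without a filter on low counts, with a range over its alternatives of an adjusted p = 0.0472 to 0.305.

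All 32 Hox genes tested rose between 50% epiboly and bud (camera adjusted p = 7.0e-17, adjusted p = 0.0634 with an estimated correlation). So did all 79 ribosomal protein genes, with a median of 1.71 log2 (adjusted p = 2.3e-39, and adjusted p = 0.0834 with an estimated correlation). All 12 retinoic acid genes rose (adjusted p = 1.7e-07), among them RARGA, a receptor, from 2.10 ± 0.68 to 94.9 ± 19.7 CPM. CYP26C1, an enzyme that breaks retinoic acid down, rose from 0.44 ± 0.37 to 39.4 ± 23.8 CPM. Every member tested rose of the anterior neural (12, adjusted p = 2.2e-10), placode (9, adjusted p = 1.3e-06) and midbrain and hindbrain (14, adjusted p = 1.7e-07) lists, with OTX2 up from 2.02 ± 1.77 to 122 ± 2.91 CPM. Of 19 maternal oocyte genes 16 fell and 2 rose (adjusted p = 4.3e-11). Of 10 germ cell genes 8 fell (adjusted p = 2.8e-06), CXCR4B from 710 ± 141 to 47.5 ± 11.4 CPM. Of 8 pluripotency factors 5 fell and 2 rose (adjusted p = 4.9e-04), POU5F3 by 3.82 ± 0.25 log2. These 7 lists, retinoic acid, anterior neural, placode, midbrain and hindbrain, maternal, germ cell and pluripotency, were the ones that held with an estimated correlation, with an adjusted p = 0.0459 to 0.0495.

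Other lists passed with the preset correlation and not with the estimated one. Up went 13 of 14 spinal cord genes with 1 down (adjusted p = 1.3e-08, and adjusted p = 0.0774 with an estimated correlation), 15 of 21 clock and Notch genes with 2 down (1.6e-05 and 0.136), and 13 of 18 paraxial genes with 3 down (3.5e-05 and 0.136). Also up were 8 of 11 prechordal genes (1.6e-04 and 0.154), 11 of 16 Wnt genes with 2 down (5.7e-04 and 0.0634), 9 of 11 epidermal genes with 2 down (0.0034 and 0.0907) and 7 of 9 notochord genes with 2 down (0.0047 and 0.0907). MYF5, the myogenic factor, rose from 0.90 ± 0.34 to 144 ± 45.7 CPM and TP63, of the epidermal basal layer, from 2.44 ± 1.25 to 135 ± 12.2 CPM. Down went 6 of 8 naive blastoderm genes with 1 up (adjusted p = 1.8e-04, and adjusted p = 0.0907 with an estimated correlation), 7 of 12 Nodal genes (0.0028 and 0.120) and 12 of 24 cell cycle genes with 5 up (0.0099 and 0.267). CCNA2 fell from 1071 ± 280 to 165 ± 11.0 CPM. The lists that did not pass were BMP (8 of 17 up, 7 down, median -0.09, mean 0.61, test upward), FGF (5 of 12 up, 2 down) and early zygotic (4 of 19 up, 11 down). Further ones were immediate early and heat shock (9 of 12 up, 3 down), enveloping layer (6 of 14 down) and plate border and crest (4 of 8 up, 3 down). The last were endoderm (4 of 9 up, 3 down), tailbud and margin (5 of 8 up, 3 down), lateral plate (3 of 5 up), blood (1 of 4 up, 2 down) and pronephros (3 of 6 up, 2 down). These 11 lists had an adjusted p = 0.0696 to 0.712. Adjusted over the list alone, 1 more gene passed in each of the maternal, Wnt, clock, blood and germ cell lists and the number was equal in the others. The test fry, which asks only whether a set moves on balance in one direction, passed 22 lists in the blastula, 29 here and 13 at the somite stages.

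The change was uneven over time. Between 50% and 60% epiboly (5.3 and 7 h) 5295 genes changed, 2637 higher and 2658 lower. Later 71 changed from 60% to 75%, 197 from 75% to 90% and 199 from 90% epiboly to bud, each 1 hour apart. NNR went from 1424 to 382 CPM, NANOG from 267 to 28.6 and H1M, a maternal linker histone, from 714 to 93.9 CPM in the first of these steps. DLX3B, a homeobox gene of the ectoderm border, went from 0.81 to 87.4 CPM. Over 2584 well-expressed genes the median absolute change was 0.44 log2 in the first step, or 0.26 per hour, and 0.19, 0.22 and 0.19 in the later steps. The DESeq2 size factors turned the split of the first step to 2204 higher and 2980 lower. In these fits, without the batch as a block, the later counts rested on single libraries. From 60% to 75% epiboly 0 genes passed in edgeR without 60% DS2 or without 60% DS4 (1164 and 1606 at an unadjusted p under 0.05, and 90 and 165 called by DESeq2). The count was 2 without 75% DS3 or without 75% DS4, 226 without 60% DS3 and 366 without 75% DS2. The complete set had 1836 genes at an unadjusted p under 0.05 and DESeq2 called 390. From 75% to 90% epiboly 47 passed without 75% DS2, 75 without 75% DS4, 395 without 90% DS2, 32 without 90% DS3 and 15 without 90% DS4. From 90% epiboly to bud 38 passed without 90% DS2, 92 without bud DS2, 40 without bud DS3 and 92 without bud DS4. With the batch as a block the 3 later steps called 445, 597 and 514 genes, and no library was left out of those fits.

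The third question was which genes changed from bud to the 6-somite stage, as somites and organ rudiments form. Bud and 6-somite come from different batches, so the contrast was taken from a curve of hours over all 28 libraries with a term for batch, which assumes 1 offset per gene and batch at all stages. ACTA1A, a skeletal muscle actin, rose from 3.10 ± 2.71 CPM at bud (SD, n = 4) to 95.8 ± 0.79 at 6-somite (SD, n = 2), by 4.00 ± 0.84 log2 in the fit (SE, edgeR adjusted p = 0.0035). LMO2, a regulator of blood and vessel progenitors, rose from 2.24 ± 0.58 to 179 ± 6.01 CPM, by 3.82 ± 0.70 (adjusted p = 8.5e-04). MDKA, a growth factor of the neural tube and somites, rose from 38.6 ± 5.07 to 421 ± 43.0 CPM, by 2.67 ± 0.34 (adjusted p = 5.4e-06). The early regulator POU5F3 fell by 3.63 ± 0.34 log2 from 98.4 ± 29.4 to 11.4 ± 2.70 CPM (adjusted p = 2.8e-08). SOX32, of endoderm, fell by 6.36 ± 0.63 from 30.9 ± 7.62 to 0.63 ± 0.33 CPM (adjusted p = 7.1e-08). GPD1B, a glycerol phosphate dehydrogenase, fell by 4.30 ± 0.52 log2 from 54.1 ± 14.3 to 2.75 ± 0.75 CPM (adjusted p = 3.0e-06).

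The other genes chosen by size were HSP90AA1.1, CLDNI, ENG2B, ZBTB16A, SOX21A, SULT2ST1 and FERMT1, which rose, and CA9, CRABP2B, PKDCCB, HESX1, STM, BLF, FRZB and SFRP1A, which fell. CLDNI, a claudin, rose from 11.4 ± 7.14 to 194 ± 8.11 CPM, and CA9, a carbonic anhydrase, fell from 86.4 ± 18.7 to 12.7 ± 3.97 CPM. In all 745 of 16345 genes changed, 344 higher and 401 lower. The count was 1990 with a curve of 3 degrees of freedom, 406 with 5, 2535 without the batch term and 1150 without a filter on low counts. The call of ENG2B (3.13 ± 0.93 log2, adjusted p = 0.0472) was lost without the 6-somite library DS5b, bud DS2 or bud DS4. That of SOX21A was lost with 5 degrees of freedom, that of BLF with 3 and that of STM with either.

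Early embryonic lists fell together into the somite stages. Of 8 naive blastoderm genes 6 fell (camera adjusted p = 1.4e-14, 7 adjusted over the list alone), of 12 Nodal genes 6 (adjusted p = 6.5e-12, 11 alone), and of 8 pluripotency factors 4 (adjusted p = 2.7e-10, 4 alone). Of 21 early zygotic genes 8 fell (adjusted p = 6.8e-10, 13 alone), and of 16 Wnt genes 6 (adjusted p = 6.8e-10, 11 alone). Of 11 epidermal genes 5 fell (adjusted p = 1.2e-07, 8 alone), of 9 endoderm genes 4 (adjusted p = 1.8e-06, 5 alone) and of 8 tailbud and margin genes 2 (adjusted p = 4.1e-05, 7 alone). WNT8A fell by 1.93 ± 0.39 log2 and CYP26A1, of the retinoic acid list, by 2.14 ± 0.36. Blood and endothelium was the list that rose with an estimated correlation, with 3 of 9 genes up (adjusted p = 5.4e-04, 5 adjusted over the list alone). Among them GATA1A, the erythroid regulator, had 0 counts at bud and 7.20 ± 2.37 CPM at 6-somite. That is at least 67.4-fold higher in raw counts, without the batch term. GATA1A passed edgeR with an adjusted p = 0.0099 and had an adjusted p = 0.555 in DESeq2, in a range over its alternatives of an adjusted p = 5.7e-08 to 0.555. SPI1B, of myeloid cells, rose by a ratio of 85.6 in raw counts, without the batch term, with a counting interval of 28.6 to 421. In the edgeR fit with that term it had an adjusted p = 0.0092. Its call was lost without the 3-somite library (adjusted p = 0.105) and without 6-somite DS5b (adjusted p = 0.248), in a range over its alternatives of an adjusted p = 3.2e-06 to 0.248. These 9 lists held with an estimated correlation, with an adjusted p = 0.00138 to 0.0381.

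A further 8 lists passed with the preset correlation alone. They were maternal (3 of 19 down, 7 adjusted over the list alone, adjusted p = 4.7e-04, and adjusted p = 0.0672 with an estimated correlation), BMP (5 of 17 down, 7 alone, 0.00115 and 0.186), retinoic acid (4 of 12 down, 6 alone, 0.00297 and 0.0672) and prechordal (2 of 12 down, 5 alone, 0.00549 and 0.288). The others were germ cell (1 of 10 down, 3 alone, 0.00549 and 0.293), cell cycle (1 of 24 down, 1 alone, 0.0254 and 0.563), Hox genes (3 of 42 up, 5 alone, 0.0240 and 0.459) and ribosomal proteins (0 of 80 past the test, 0 alone, median 0.32, 8.6e-05 and 0.730). Not past camera were FGF (1 of 12 down), clock and Notch (0 of 21), and immediate early and heat shock (1 of 17 down). The same was true of globins (0 of 4, median -0.61, mean -0.34, test upward), yolk syncytial layer (0 of 5, median -0.06, mean 0.78, test upward), and enveloping layer (0 of 14). It was true of plate border and crest (2 of 9 up and 2 down, 7 alone, median -0.65, mean 0.43, test upward), placode (0 of 9), anterior neural (3 of 13 up, 2 down, 6 alone, median -0.29, mean 0.26, test downward) and midbrain and hindbrain (1 of 15 up, 2 down, 6 alone). The rest were spinal cord (0 of 14, median 0.13, mean 0.20, test downward), notochord (1 of 10 up, 1 down, 4 alone), paraxial (1 of 18 down, 2 alone), lateral plate (2 of 10 up, 4 alone) and pronephros (1 of 8 down, 1 alone). These lists had an adjusted p = 0.0558 to 0.914. FOXG1A, the forebrain regulator of the anterior neural list, rose from 1.11 ± 1.39 to 28.1 ± 4.56 CPM, by 5.14 ± 1.06 log2 (adjusted p = 0.0030). In the lists with 0 genes past edgeR, the counts at an unadjusted p under 0.05 were 1 for ribosomal proteins and the yolk syncytial layer, 2 for clock and Notch, placode and spinal cord, 3 for the enveloping layer and 0 for globins. DESeq2 called 0 genes in these 7 lists.

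The fourth question was which cell populations made up the gastrula and how their shares moved. Cells from 50% epiboly to bud were clustered together, and 19 of 25 clusters, with 72.37% of 29177 cells, took the names of 13 classes from marker lists. Spinal cord-like cells (clusters 4 and 12) made up 0% of cells at 50% epiboly, where a count of 0 allows up to 0.0512%. They made up 1.61 ± 1.74% at 60%, 10.1 ± 4.26% at 75%, 19.2 ± 3.19% at 90% epiboly (SD, n = 3 each) and 19.9 ± 2.65% at bud (SD, n = 4). Midbrain and hindbrain-like cells (cluster 5) went from 0.127% at 60% epiboly to 13.98 ± 1.33% at bud, and heart and lateral plate-like cells (cluster 17) from 0%, with an upper limit of 0.0714%, to 5.98 ± 0.637%. Tailbud and margin-like cells (cluster 7) went from 18.1 ± 3.10% at 60% and 14.5 ± 3.06% at 75% to 2.07 ± 2.27% at 90% epiboly and 0.0053% at bud. Shares depend on which clusters took a name in each window. At 3-somite, clustered apart, tailbud and margin-like cells held 8.95% and spinal cord-like cells 6.93%, and cluster 12, named spinal cord here, had tailbud and margin as its next class. Neither the tailbud value near 0 nor the spinal cord share at bud therefore measures how many such cells the embryo held. Notochord-like cells (cluster 15) went from 3.70 ± 0.379% at 60% to 2.03 ± 0.894% at bud.

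Over the 17 libraries the share rose with hours for the clusters named spinal cord (Pearson r = 0.92, permutation p = 1e-05, adjusted p = 6.5e-05, Spearman rho = 0.93). The share rose for midbrain and hindbrain (r = 0.88, permutation p = 2e-05, adjusted p = 8.7e-05, rho = 0.97). It also rose for lateral plate (r = 0.86, permutation p = 1e-05, adjusted p = 6.5e-05, rho = 0.96). The tests were two-sided, with hours permuted within batch and 13 classes in the family. The permutation p of each rho was 1e-05 (adjusted p = 4.3e-05), the smallest that 100000 permutations can give. Without the 2 libraries farthest from the median hour r was 0.91, 0.89 and 0.87. Within DS2, DS3 and DS4 it was 0.93, 0.90 and 0.94 for spinal cord, 0.87, 0.90 and 0.92 for midbrain and hindbrain, and 0.88, 0.88 and 0.84 for lateral plate. The 50% epiboly libraries, of which 94.1% of cells stayed unnamed, lie apart from the rest for the other classes. These were also taken over the 13 libraries from 60% epiboly on, an alternative chosen after seeing the data. There the share of the cluster named tailbud and margin fell (r = -0.93, permutation p = 1.5e-04, adjusted p = 8.2e-04, rho = -0.96, permutation p = 9e-05, adjusted p = 4.8e-04). Its r was -0.92 without the 2 farthest and -0.93, -0.95 and -0.94 within DS2, DS3 and DS4. The notochord share fell as well (r = -0.67, permutation p = 0.0147, adjusted p = 0.0382, rho = -0.74, permutation p = 0.00906, adjusted p = 0.0236). From 60% epiboly on the notochord r was -0.67 without the 2 farthest and -0.77, -0.88 and -0.61 within these batches. Over all 17 libraries it was 0.45 (permutation, adjusted p = 0.113), of the opposite sign. Over all alternatives, whichever the direction, the range was an adjusted p = 8.2e-04 to 0.634 for tailbud and margin and 0.0167 to 0.395 for notochord. The low end for notochord is not that of the fall from 60% epiboly on (permutation, adjusted p = 0.0382).

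For the other classes no correlation with hours passed from 60% epiboly on. Epidermal ectoderm-like cells (cluster 6 at 60% and 75%, cluster 1 at 90% epiboly and bud) made up 19.8 ± 3.28% at 60% and 19.3 ± 2.23% at bud (r = 0.01 from 60% epiboly on, adjusted p = 0.953). Paraxial mesoderm-like cells (cluster 2, then clusters 11 and 19) made up 16.9 ± 2.35% and 16.9 ± 3.58% (r = -0.08, adjusted p = 0.887). Anterior neural-like cells (cluster 3, then 13 at bud) made up 5.97 ± 0.713% at 60%, 15.7 ± 6.30% at 75% and 10.9 ± 1.94% at bud (r = 0.26, adjusted p = 0.456). Endoderm-like cells (cluster 14) made up 4.08 ± 0.843% and 2.497 ± 0.721% (r = -0.48), and prechordal plate-like cells (cluster 20) 2.67 ± 0.497% and 1.496 ± 0.621% (r = -0.57). Enveloping layer-like cells (cluster 22, of 50% epiboly, and cluster 23) made up 0.257% and 0.719 ± 0.362%, after 2.76 ± 0.723% at 50% epiboly. Germ cell-like cells (cluster 24) made up 0.219% and 0.125%. These classes had an adjusted p = 0.133 to 0.172 from 60% epiboly on. Over all 17 libraries Pearson's r also passed for epidermal, paraxial and anterior neural cells, upward, and for the enveloping layer, downward. Spearman's rho did not for paraxial (0.45, adjusted p = 0.144) and enveloping layer cells (-0.30, adjusted p = 0.291). From 60% epiboly on none of these 4 passed, and the paraxial and enveloping layer values had the opposite sign, as did those of endoderm and prechordal cells. At a clustering resolution of 2.0 the endoderm and prechordal correlations over the 17 libraries turned from 0.52 (adjusted p = 0.0692) and 0.48 (adjusted p = 0.0872) to -0.82 (adjusted p = 2.6e-04) and -0.80 (adjusted p = 4.8e-04). Without batch DS2 the prechordal one was -0.78 (adjusted p = 0.0207). The range over all alternatives, whichever the direction, was an adjusted p = 2.6e-04 to 0.224 for endoderm, 4.8e-04 to 0.395 for prechordal and 0.00767 to 0.224 for enveloping layer cells. It was an adjusted p = 4e-05 to 0.953 for epidermal, 3.7e-04 to 0.887 for paraxial and 1.3e-04 to 0.759 for anterior neural cells. Unnamed clusters held 24.2% of cells at 60%, 11.5 ± 10.3% at 75%, 7.14% at 90% epiboly and 5.90% at bud, where the naming threshold was set after a first set of clusters had been seen.

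**Figure D2:**
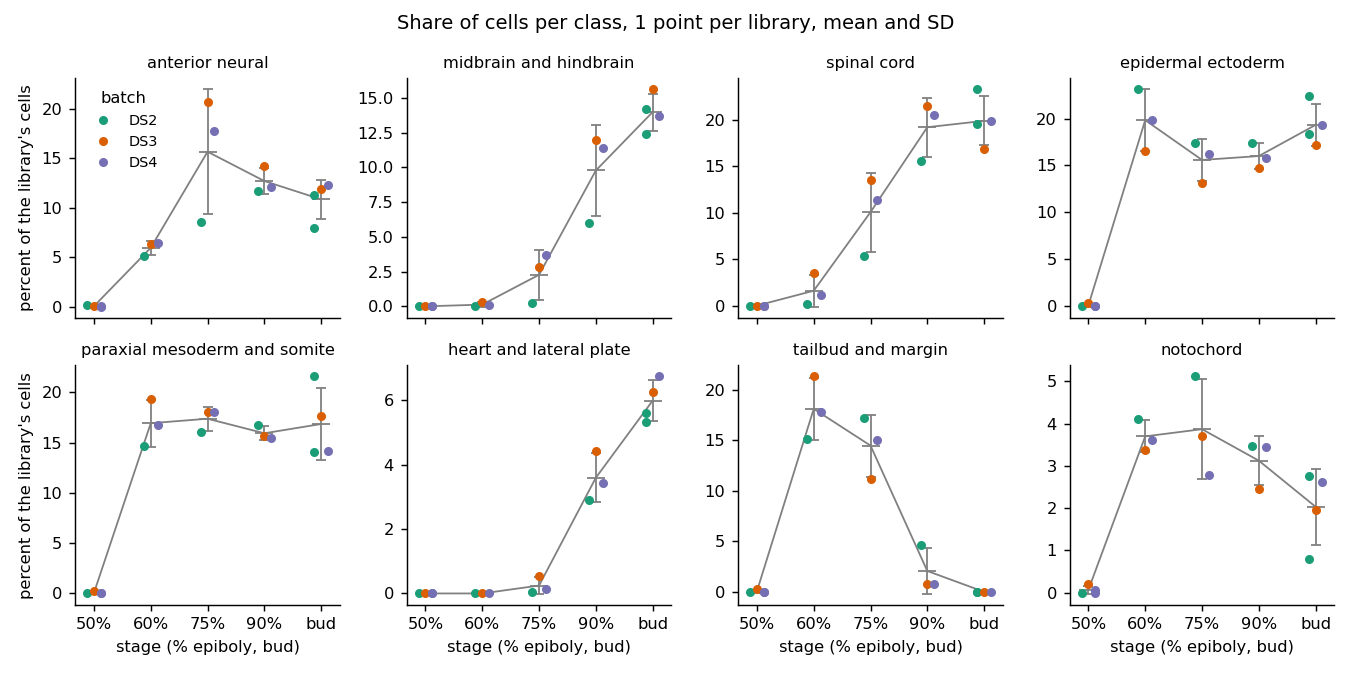
Percentage of a library's cells in each of 8 named classes (linear axes) against stage, from 50% epiboly to bud, with a point per library coloured by batch and lines for the mean with SD bars. The clusters named spinal cord reach 19.9% and midbrain and hindbrain 13.98% at bud. The cluster named tailbud and margin drops from 18.1% at 60% epiboly to 0.0053% at bud.

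Populations that part early were sought from high to shield, with markers of the enveloping layer, the outer epithelium of the embryo, and of the germ line. Enveloping layer-like cells (clusters 10 and 13) made up 3.86% of cells at high (12 of 311, exact 95% interval 2.01 to 6.64) and 7.00% at oblong (3.88 to 11.5). These pooled values differed between libraries, with 4.56% in high DS5 and 0% of 48 cells in high DS5b, and 2.78% in oblong DS5 and 9.38% in oblong DS5b. They made up 5.88% at dome (4.60 to 7.38), 3.78% at 30% epiboly (2.88 to 4.88) and 1.15% at shield (0.594 to 2.00). At shield 29.6% of cells were paraxial mesoderm-like (cluster 4, 26.9 to 32.5), 4.59% prechordal plate-like (cluster 11, 3.40 to 6.04) and 2.49% endoderm-like (cluster 14, 1.63 to 3.62). At 30% epiboly 14.6% were margin-like (cluster 8, 12.9 to 16.5). No cluster took the germ cell name, and germ cells could not be told apart here. At least 3 UMIs of that panel, which holds maternal transcripts, were found in 100% of cells at high (median 7248 UMIs) and 52.9% at shield (median 2904), or 34.5% at shield with each cell thinned to 2000 UMIs. Unnamed clusters held 96.1% of cells at high, 93.0% at oblong, 93.3% at dome, 79.5% at 30% epiboly and 61.3% at shield. No test was made of these shares, and a cluster almost wholly of shield may be that library. By at least 3 UMIs of its markers the enveloping layer share was 6.04% at 30% epiboly and 4.68% at shield, or 4.32% and 2.58% thinned to 2000 UMIs. It was 0% at high and oblong at resolutions 0.6 and 2.0 and without cells called doublets.

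At the somite stages 19 of 25 clusters, with 90.92% of 6091 cells, took 14 names. The largest shares at 6-somite were paraxial mesoderm-like (clusters 0, 10 and 19, 17.7 ± 0.908%, SD, n = 2), midbrain and hindbrain-like (clusters 1 and 8, 13.6 ± 2.02%) and anterior neural-like cells (clusters 3 and 9, 12.6 ± 1.98%). At 3-somite, with 1 library, these made up 15.3% (exact 95% interval 13.6 to 17.2), 15.6% (13.8 to 17.4) and 10.2% (8.81 to 11.8). Classes whose name no cluster took in the gastrula were placode-like (cluster 5, 7.54% at 3-somite with an interval of 6.31 to 8.93, and 5.43 ± 0.658% at 6-somite) and neural plate border and crest-like (cluster 11, 3.49%, 2.66 to 4.50, and 4.12 ± 1.36%). Another was blood and endothelium-like cells (cluster 15, 1.53%, 0.994 to 2.25, and 2.47 ± 0.512%). Epidermal ectoderm-like cells (clusters 6 and 13) made up 6.56% (5.41 to 7.87) and 8.93 ± 0.663%, and tailbud-like cells (cluster 2) 8.95% and 8.14%. Spinal cord-like cells (cluster 4) made up 6.93% and 6.24 ± 2.64%, and lateral plate-like cells (cluster 7) 6.44% and 4.91 ± 1.51%. Endoderm-like cells (cluster 12) made up 3.80% and 3.42%, notochord-like (cluster 17) 1.84% and 2.03%, prechordal and hatching gland-like (cluster 22) 0.797% and 1.01%, and enveloping layer-like cells (cluster 23) 0.368% and 0.859%. Unnamed clusters held 10.6% and 8.54%. No test was made between these stages.

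Expression of the cells that took 1 class name was compared between 60% epiboly and bud on counts summed per library and class. Anterior neural, epidermal and paraxial cells lay mostly in different clusters at the 2 stages (cluster 3 then 13, 6 then 1, and 2 then 11 and 19), so these differences do not separate a change of expression from a change in which cells took the name. In anterior neural-like cells CDH6, a cadherin, had 0 counts at 60% epiboly and 81.4 ± 42.5 CPM (SD, n = 4) at bud, at least 21.3-fold higher (edgeR adjusted p = 6.4e-05). FZD8B, a Wnt receptor, rose by a ratio of 93.5 with a counting interval of 16.7 to 3701 (adjusted p = 6.9e-05). POU5F3 fell by 5.68 ± 0.40 log2 (SE) from 1045 ± 307 to 21.3 CPM (adjusted p = 1.5e-09). FOXI1, a regulator of epidermal ectoderm, fell from 65.8 ± 33.2 to 0.54 CPM, a ratio of 68.2 with an interval of 21.9 to 343 (adjusted p = 1.4e-06). In epidermal-like cells DMBX1A and SIX3B, homeobox genes of the anterior neural plate, rose from 0.21 to 79.2 CPM and from 0.47 to 113 CPM. Their ratios were 406 (interval 72.4 to 16071, adjusted p = 2.1e-06) and 379 (105 to 3140, adjusted p = 1.9e-07). LHX5 fell by 4.84 ± 0.44 log2 from 75.3 ± 9.84 to 2.38 CPM (adjusted p = 2.6e-07). In paraxial-like cells HOXB1B rose by 5.44 ± 0.67 log2 from 2.2 to 100 CPM (adjusted p = 7.0e-06). HER12, a segmentation clock gene, rose by 5.11 ± 0.53 from 1.85 to 75.0 CPM (adjusted p = 1.2e-06), and MIXL1 fell by 6.34 ± 0.77 from 123 ± 73.2 to 1.40 CPM (adjusted p = 6.2e-06).

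SOX21A and KAZALD2 were the other anterior neural genes chosen by size, KAZALD2 lower by a ratio of 150 (interval 39.9 to 1265). ZNF503, NNR and NDRG1A were the other epidermal ones, of which NNR fell by 4.86 ± 0.34 log2 from 541 ± 191 to 19.2 CPM. MLLT3, ELOVL6 and DDX4 were the other paraxial ones, ELOVL6 lower by a ratio of 267 (91.0 to 1297). The test called 1407 of 5562 genes in anterior neural-like cells, 672 higher and 735 lower. It called 2889 of 7386 in epidermal-like cells, 1451 higher and 1438 lower, and 2631 of 7144 in paraxial-like cells, 1310 higher and 1321 lower. The 13 libraries had at least 20 cells each and summed totals of 164497 to 2549181 UMIs.

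Endoderm, notochord and prechordal classes had under 20 cells in both bud DS2 libraries and were compared over 11 libraries, 3 at 60% epiboly against 2 at bud, a choice made after seeing the counts. In notochord-like cells HOXC3A and COL11A1A, a fibrillar collagen, had 0 counts at 60% epiboly and were at least 98.5-fold and 71.8-fold higher at bud. GSC, the goosecoid homeobox gene of the prechordal plate, had 502 ± 160 CPM (SD, n = 3) at 60% epiboly and 0 at bud, at least 87.1-fold lower (adjusted p = 7.3e-05). APLNR2 was at least 72.4-fold higher, and CYP24A1 at least 12.7-fold lower. In prechordal-like cells NEFMB was at least 58.0-fold higher (adjusted p = 8.4e-06), SAMD7 at least 29.9-fold and PKIB at least 25.8-fold. PCDH8, a paraxial protocadherin, was at least 49.7-fold lower (adjusted p = 1.3e-04), EFNB2B at least 34.0-fold and GATA5 at least 28.7-fold. In endoderm-like cells PRDM1A was at least 50.3-fold higher (adjusted p = 8.6e-07), HOXB1B at least 59.2-fold and HOXC3A at least 51.0-fold. DDX4, a germ cell gene, was lower by a ratio of 194 (interval 34.6 to 7668, adjusted p = 2.2e-05), VGLL4L by 84.3 (23.2 to 699) and NNR by 60.3 (16.5 to 501). These fits called 972 of 4856, 1452 of 4309 and 1471 of 3877 genes in endoderm, notochord and prechordal cells, and 275, 837 and 846 without the library bud DS3.

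Cell cycle genes fell in each of these 6 classes. In notochord-like cells 20 of 24 fell (camera adjusted p = 1.6e-12, 21 adjusted over the list alone, and adjusted p = 0.205 with an estimated correlation), with a median of -2.01 log2. In prechordal-like cells 18 of 24 fell (adjusted p = 1.3e-06, 18 adjusted over the list alone, and adjusted p = 0.147 with an estimated correlation), with a median of -1.54. The list fell in epidermal (17 down, 1 up, 19 alone, median -0.62, adjusted p = 1.6e-07) and anterior neural cells (12 down, 2 up, 14 alone, median -0.55, adjusted p = 8.6e-04), where it also passed with an estimated correlation (adjusted p = 0.0259 and 0.0229). It fell in paraxial (13 down, 1 up, 15 alone, median -0.48, adjusted p = 1.5e-04) and endoderm cells (7 down, 1 up, 11 alone, median -0.45, adjusted p = 0.00353), where it did not (adjusted p = 0.0587 in both with an estimated correlation). Summed over the list, notochord-like cells went from 6232 ± 719 CPM at 60% epiboly (SD, n = 3) to 1523 ± 344 at bud (SD, n = 2). Paraxial-like cells went from 9290 ± 352 to 6002 ± 282 CPM (SD, n = 4). The difference between notochord and paraxial cells in log2 CPM fell with hours over 11 libraries (Pearson r = -0.88, permutation p = 1.6e-04, adjusted p = 4.0e-04 over 5 comparisons). Spearman rho was -0.89 (permutation p = 3.5e-04) and r was -0.79 without the 2 libraries farthest from the median hour. The difference changed by -1.02 from 60% epiboly to bud in DS3 and by -1.69 in DS4.

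**Figure D3:**
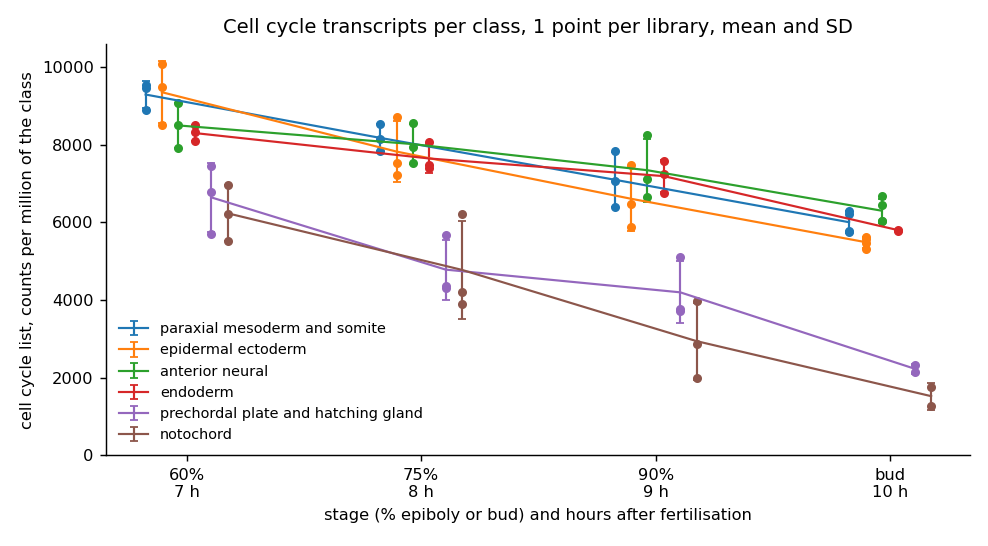
CPM of the cell cycle list within 6 classes (linear axis from 0) against hours after fertilization, from 60% epiboly to bud, with a point per library and the mean with SD. Notochord drops from 6232 to 1523 and prechordal from 6642 to 2228, while paraxial mesoderm goes from 9290 to 6002.

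Other lists moved within classes. All 22 Hox genes tested rose in paraxial-like cells (camera adjusted p = 2.2e-25, and adjusted p = 0.030 with an estimated correlation). Naive blastoderm genes fell in anterior neural (7 of 8, adjusted p = 3.3e-15), epidermal (6 of 8) and paraxial cells (6 of 7), in each with an estimated correlation too (adjusted p = 0.00281, 0.0307 and 0.0300). The BMP list fell in anterior neural cells (8 of 11, adjusted p = 2.0e-09 and 0.0136 with an estimated correlation) and so did the epidermal list (6 of 7, adjusted p = 1.2e-07 and 0.0229). In epidermal-like cells, cluster 6 at 60% epiboly and cluster 1 at bud, 5 of 10 genes of the epidermal list itself rose and 1 fell (adjusted p = 0.0337, and adjusted p = 0.327 with an estimated correlation). The placode list rose there (6 of 6, adjusted p = 9.1e-08 and 0.0307 with an estimated correlation) and so did the anterior neural list (8 of 9, with 1 lower, adjusted p = 2.1e-07 and 0.0308). The prechordal list rose there as well (6 of 7, adjusted p = 5.8e-07 and 0.0307 with an estimated correlation). The midbrain and hindbrain (5 of 5, adjusted p = 0.0045 and 0.109) and Hox lists (7 of 7, adjusted p = 1.3e-04 and 0.174) passed only with the preset correlation. In endoderm-like cells the spinal cord list, which holds Hox genes, rose (5 of 5, adjusted p = 1.3e-10 and 0.0264 with an estimated correlation) and the paraxial list fell (3 of 7, adjusted p = 2.3e-05 and 0.0297). Nodal genes fell in paraxial cells (5 of 7, adjusted p = 4.0e-07 and 0.0106 with an estimated correlation) and in prechordal cells (7 of 8, adjusted p = 3.1e-04 and 0.181). Ribosomal protein genes rose in all 6 classes, from 57 of 79 in endoderm to 78 in anterior neural, epidermal and paraxial cells. They passed with an estimated correlation in anterior neural cells (adjusted p = 0.0458, against 0.0849 to 0.205 in the rest). Of the lists tested 14 of 22 passed camera in anterior neural cells, 16 of 26 in epidermal, 18 of 30 in paraxial, 12 of 29 in endoderm, 11 of 25 in notochord and 13 of 20 in prechordal cells. With an estimated correlation 10, 7, 5, 2, 0 and 0 of these held. In notochord and prechordal cells 4 and 3 lists had an unadjusted p under 0.05 with that estimate, and fry passed 20 and 16.

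The last question was how the 2 axial fates, notochord and prechordal plate, part. The notochord panel was NOTO, TA, SHHA, COL2A1A and LOXL5B, with 1 further gene not found in the table, and the prechordal panel was GSC, FRZB, CTSLB, HE1A, HE1B, KLF17 and FZD8B. Among cells of all types with at least 2 UMIs of either panel 8.76 ± 3.04% carried both at 60% epiboly (SD, n = 3, 163 of 1831 cells) and 6.84 ± 2.43% at bud (SD, n = 4, 117 of 1654). The difference was -1.92 percentage points (exact permutation p = 0.400, two-sided, smallest possible 0.0286), and -5.46, 1.35 and -1.54 within DS2, DS3 and DS4. Thinned to 2000 UMIs per cell the shares were 6.33 ± 1.23% and 5.36 ± 2.80% (exact permutation p = 0.686). The background, notochord with enveloping layer genes, was 5.15 ± 2.07% and 7.25 ± 2.97%, or 1.23% and 2.55% thinned. At 60% epiboly 46.9% of paraxial-like cells carried the notochord panel when thinned, and at bud 15.7% of epidermal-like cells (13.5 to 18.2) carried the prechordal panel.

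Within the notochord-like and prechordal-like classes, a set chosen after that result was seen, 42.96 ± 3.65% of cells carried both panels at 60% epiboly (116 of 269), 22.3 ± 6.69% at 75%, 8.57 ± 5.57% at 90% epiboly and 3.81 ± 2.83% at bud (12 of 280). The exact permutation p = 0.0286 was the smallest that 35 splits can give, and with the 12 splits kept within batches it was 0.0833, also the smallest possible. The difference was -43.9, -39.5 and -33.0 points within DS2, DS3 and DS4. With classes clustered without the panel genes and cells thinned, the shares at the ends were 27.47 ± 3.33% and 1.59 ± 2.67% (exact permutation p = 0.0286). Notochord-like cells carried the prechordal panel in 41.4% of thinned cells at 60% epiboly (exact 95% interval 33.5 to 49.7, median 5282.5 UMIs before thinning) against 1.09% of epidermal-like cells (0.501 to 2.07, median 5867). At bud it was 0.901% (median 3287.5). These UMIs in notochord-like cells at 60% epiboly were mainly of GSC (48.1%, seen in 47.4% of cells) and FRZB (36.5%, seen in 51.9%), with KLF17 in 8.97% and FZD8B in 18.6%. In prechordal-like cells of that stage these were seen in 99.1%, 99.1%, 92.0% and 92.0%, while HE1A and HE1B, of the hatching gland, were seen in 0% of either class. Without GSC the panel was carried by 27.6% of thinned cells (20.7 to 35.5). The bud libraries of DS2 held 5 and 18 cells of these classes. Within these classes the background, notochord with enveloping layer genes, was 8.11 ± 4.95% at 60% epiboly (15 of 192) and 26.9 ± 27.1% at bud (19 of 166). The bud mean rests in part on bud DS2, with 2 of 3 cells. Thinned, the background was 2.01 ± 1.85% and 4.09 ± 3.42%, so the share with both axial panels at bud was not above it.

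**Figure D4:**
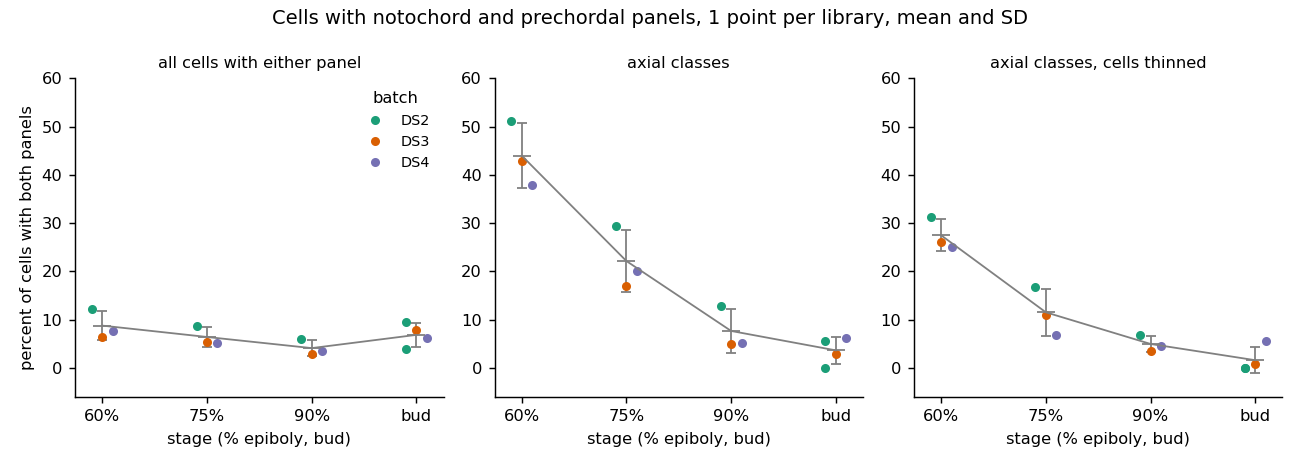
Percentage of cells with both axial panels (linear axes) against stage, from 60% epiboly to bud, over all cells with either panel, in axial classes clustered without the panel genes, and in those classes thinned to 2000 UMIs per cell, with a point per library coloured by batch and the mean with SD. The share in axial classes drops from 44.0% to 3.63%, or from 27.5% to 1.59% thinned, while over all cells it is 8.76% and 6.84%.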

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

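The tests of depth, number of libraries, interval, mixture, batch, free RNA, random doublets and panel genes below were chosen only after the results were seen, while the splits of the samples were chosen before.

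Cell cycle transcripts fell further in the 2 axial classes than in paraxial mesoderm, and the difference from paraxial cells along the hours was tested directly for 5 classes (notochord r = -0.8805, prechordal r = -0.837, anterior neural r = 0.9029, endoderm r = 0.6278, epidermal r = -0.6958). Paraxial or margin cells counted among axial cells at 60% epiboly, each taken alone, do not account for all of it. Their markers reached at most 43.267% of the level in their own class and 48.4% or more was needed. In prechordal cells the mean was 39.8% for paraxial markers, with 62.2% needed, and 4.53% for margin markers, with 56.6% needed. In notochord cells it was 15.8% (60.5% needed) and 27.4% (55.5% needed). A part of the fall is therefore not excluded, and a mix of both was not tested. A few genes taking more of the counts at bud do not account for the fall. Other well-counted genes changed by a median of -0.2528 log2 in prechordal and -0.1609 in notochord cells, against -1.5757 and -2.0332 for the cell cycle genes. Batch does not, since the difference changed by -0.788 to -1.6924 within DS3 and DS4. A hypothesis that remains, not tested on other data, is that axial cells may leave the cell cycle earlier than paraxial cells, and the bud value rests on 2 libraries (DS3 and DS4).

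The step from 50% to 60% epiboly called more genes than later steps. Depth alone does not account for it, since with every library thinned to 1 total it called 3377 genes and the later steps 47 to 100. The number of libraries does not, since with 1 library per stage and batch it called 4814 and the later steps 54 to 196. The longer interval of 1.7 h argues for part of the gap, since 2-hour steps called 2846 genes from 60% to 90% epiboly and 2832 from 75% epiboly to bud. These stayed below 4019, the lowest count of the first step without 1 library. Neither the 2-hour counts nor the 4019 were thinned, and depth and interval together were not tested. The counts in this paragraph also come from fits without the batch as a block. A fit with that block raised the counts of the later steps, so how much of the gap the interval explains is not settled. By median absolute change per hour the gap was smaller, with 0.26 log2 in the first step and 0.19, 0.22 and 0.19 later. Whether the rest may reflect a faster turnover at the start of gastrulation was not tested.

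The share of axial cells with both panels fell from 60% epiboly to bud. Depth does not account for it, since in cells thinned to 1 depth the share still changed by -24.3426 percentage points (exact permutation p = 0.0286). Clustering on the panel genes does not either, since in classes clustered without them the share changed by -40.3571 points. These clusters were still named from marker lists that hold panel genes, and an effect of that naming was not tested. Free RNA does not account for the fall. At most 1.0936% of epidermal and paraxial cells carried the prechordal panel at 60% epiboly, with an upper limit of 2.16%, against 41.4% of notochord cells with a lower limit of 33.5%. Doublets of cells paired at random would put that panel in epidermal and paraxial cells too, where the highest upper limit of its share was 2.1632%. Such a doublet may cluster outside those classes, so this value does not exclude random doublets. Axial neighbours left joined pair more often than chance, and the doublet caller did not settle them. Joined cells would carry the whole panel. Of panel UMIs in notochord cells at 60% epiboly KLF17 made up 2.80% and FZD8B 12.5%, against 15.7% and 25.0% in prechordal cells. GSC (48.1%) and FRZB (36.5%) made up more, against 28.8% and 29.0%. These values argue against joined cells as the whole account, and a part stays open. The splits kept within batches, 12 in number, are too few to decide on the fall. The panel in notochord cells was mainly GSC and FRZB, so a hypothesis, which needs other data, is that early notochord cells may share these 2 genes with prechordal cells.

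Regrouping the libraries gave counts as large only for the real stages. For bud and 50% epiboly 1 of 35 splits called as many genes (7941 against 0 in the highest other). For 60% and 50% epiboly it was 1 of 35 (5295 against 3947). For bud and 90% epiboly it was also 1 of 35 (199 against 135, in the split that sets the 90% libraries and bud DS2b against the rest). The share was thus under 0.05 in these 3 by splits that ignore batch. Libraries of 1 batch deviate together, so such splits do not exclude chance. Splits kept within batches numbered 18, 12 and 12, too few for a share under 0.05, with 0, 1827 and 135 genes in the highest other. The 3947 genes of another split point to a structure of the samples, of which the stages themselves are a part. For 75% and 60% epiboly (71 against 8) and for 90% and 75% (197 against 0) 10 splits are too few for a share under 0.05, and the real split gave the highest count, 1 of 10. Within anterior neural, epidermal and paraxial cells 1 of 35 splits called as many genes as the stages (1407 against 453, 2889 against 1570 and 2631 against 1538). These splits ignore batch too and do not exclude chance, and the high counts of other splits may reflect a structure of the samples, the stages included. Within batches there were 12 splits in each, too few, with 453, 1570 and 1538 genes in the highest other.

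A library stood far from the other 3 of its stage in 27 of 312 groups tested. In 13 of these the other 3 held 0, where even 1 count always passes, so the zeros fix that outcome. Of the 291 groups without 3 values at 0, 14 stood apart (4.81%), where chance gives about 1 in 20. Of all 27, 12 were at 50% epiboly in DS3, 5 in DS2, 2 in DS4 and 1 in DS4b. DS3 had 4.65 CPM of OTX2 (others 0.97 to 1.45), 2.79 of SHHA (0.24 to 0.67), 3.46 of TBX1 (1.09 to 1.34), 47.08 of SP5A (25.20 to 27.17), 565.78 of RPS10 (484.87 to 494.17) and 0.13 of each of HOXB7A, HOXB3A, LSP1 and SIX1B (others 0), and it held 0.5594% endoderm-like, 0.2098% paraxial-like and 0.2797% tailbud and margin-like cells (others 0). DS2 had 53.43 CPM of FGF8A (27.94 to 29.66), 12.9 of MSX1B (27.40 to 29.93), 2.07 of TLL1 (0.56 to 0.80), 0.37 of PAX3A and 0.12 of FOXF2A (others 0). DS4 had 0.22 of HOXC9A and 0.0638% prechordal-like cells (others 0), and DS4b 0.1 of EGR1 (others 0). At bud DS2 had 87.02 CPM of HER2 (54.42 to 57.20), 66.38 of HAND2 (36.14 to 41.03) and 2.23 of DLX4B (5.13 to 5.69), DS2b had 6.84 of LHX1A (9.39 to 9.87), and DS3 had 5.44 of EGR1 (2.28 to 2.79), 12.28 of CA15B (0.56 to 0.57) and 0.021% tailbud and margin-like cells (others 0).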

How the results depend on the processing

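The alternatives named as thinned to 1 total, 1 library per stage and batch, without both bud libraries of DS2, libraries from 60% epiboly on, axial classes and without GSC were chosen only after the data were seen. Counts of changed genes stayed within 1.5 times the reported value in every alternative run for the blastula trend (4575 to 5486 with 1 library left out, 6013 without a filter), bud against 50% epiboly (7244 to 7805, 8921 without a filter, 8338 with the batch as a block) and, apart from thinning, 60% against 50% epiboly (4019 to 5399, 5947 with the block). Thinned to 1 total the steps called 3377 genes from 50% to 60% epiboly, 47 to 75%, 90 to 90% and 100 to bud, where fewer genes were tested. The later steps moved most. From 60% to 75% epiboly (71 reported) DESeq2 called 390, no filter 437, the replicate block 445, and leaving out 1 library gave 0 to 366. From 75% to 90% (197) the values were 507, 486, 597 with the block, and 15 to 395. From 90% epiboly to bud (199) they were 418, 558, 514 with the block, and 38 to 214, with 86 for 1 library per stage and batch and 130 without both bud libraries of DS2. For 6-somite against bud (745) they were 1150 without a filter, 1990 with a spline of 3 degrees of freedom, 406 with 5, 2535 without the batch term, and 515 to 964 with 1 library left out. The block changed no other call of a count, within classes included (1535, 3117, 2877, 884, 1375 and 1368 for anterior neural, epidermal, paraxial, endoderm, notochord and prechordal cells). With 1 library left out, classes called 1085 to 1323 genes in anterior neural, 2218 to 2810 in epidermal, 2024 to 2584 in paraxial, 275 to 972 in endoderm, 837 to 1360 in notochord and 846 to 1426 in prechordal cells, where the lowest left 1 bud library, assumed to vary like the other stages. With an estimated correlation 0, 7 and 9 gene lists passed in the blastula, gastrula and somite contrasts, against 19, 20 and 17. Of 521 results for single lists 447 stayed on their side of the threshold, 19 passed only in the alternative and 55 only in the reported setting, 40 of them through the estimated correlation.

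Among 3814 values of named genes 3652 stayed on their side, 90 passed only in an alternative, 71 only as reported and 1 turned (IRX7, blastula trend). Its slope of 0.06 (adjusted p = 0.789) was -0.8238 (adjusted p = 0.00466) without the shield library, with -0.8238 to 0.1642 over the libraries left out and an adjusted p = 0.00466 to 0.891 over its alternatives. Of 359 within classes 358 stayed. The correlation of a share with hours turned sign with libraries from 60% epiboly on for the enveloping layer (0.4796 from -0.6633), notochord (-0.6709 from 0.4459) and paraxial cells (-0.0776 from 0.7775), and past no test for endoderm (-0.4778 from 0.519) and prechordal cells (-0.5685 from 0.4848). It turned at resolution 2.0 for endoderm (-0.8156) and prechordal cells (-0.8043), and for the latter without batch DS2 (-0.7787), and the cause was not tested beyond the gap between 50% epiboly and later stages. The number of classes past the test was 5 to 9 against 7. The enveloping layer share was 0% at high and at oblong (3.8585% and 7.00% reported) at resolutions 0.6 and 2.0 and without called doublets, since no cluster there kept the name. By at least 3 UMIs of its markers it was 6.0425% at 30% epiboly (3.7849%) and 4.6845% at shield (1.1472%), and thinned 1.9737% at high and 2.5773% at shield. In axial classes the share of cells with both panels changed by -39.148 points, -24.3426 thinned, -40.3571 clustered without the panel genes, -25.8822 with both, and without GSC -32.174, or -19.6721 thinned (exact permutation p = 0.0286 each, 0.0833 with splits kept within batches), against -1.918 (exact permutation p = 0.4) over all cells, which was -3.08 to -0.198 with 1 library left out. In the somite contrast the test on simulated data recovered 3.57% of changes of 1 log2, the lowest share of the fits over all cells, and p-values cover only these libraries.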

Other observations

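The low-oxygen genes and the test of genes uneven between libraries were chosen only after their values were seen.

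Clusters without a class name at the somite stages held recognisable groups of genes, named here after their leading genes were seen. A cluster led by ELAVL3, NEUROD1 and NEUROD4, genes of neuronal differentiation, held 115 cells, 2.21% at 3-somite and 1.77% at 6-somite. A cluster of 65 cells led by CFAP45, FOXJ1A and SHHA, of motile cilia and the ventral midline, made up 1.29% and 0.987%, and a cluster of 131 cells led by NKX2.4B, NKX2.1 and SHHA made up 2.09% and 2.18%. Cells led by GCM2, FOXI3A and FOXI3B, regulators of ionocytes, numbered 32 (0.429% and 0.561%), and those led by TWIST1A and FOXL2 numbered 144 (2.58% and 2.29%). A cluster of 66 cells led by FABP2, APOA1B and AFP4, genes of lipid transport, made up 2.02% and 0.74%, with a median depth of 0.525 of its libraries' median. Inside the paraxial class a cluster of 79 cells led by ACTA1A, MYL10 and MYOD1 made up 0.981% and 1.41%. Each stage had 1 or 2 libraries, so no difference between them was tested.

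Before gastrulation, a cluster of 238 cells led by NANOS3, DND1, CA15B and BTG4, all maternal transcripts, held 89.5% of the cells at oblong and 16.1% at high, and with so few cells and 2 libraries per stage it is not shown to be a cell type. A cluster of 163 cells led by GSC, CHD, FOXA3 and LFT1, genes of the dorsal organizer, made up 8.52% at dome and 4.12% at 30% epiboly. In the gastrula, 706 cells of an unnamed cluster were led by TWIST1A, FSTA and RIPPLY1, and 328 by NKX2.4B, SHHB and LFT2.

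Of 7 genes known from the response to low oxygen, picked after their values were seen, all 7 were highest in 60% DS3 and in 90% DS2 among the libraries of their stage, with sums of 466.68 CPM (146.17 and 195.73 in the others) and 657.89 (222.39 and 269.35). At 60% epiboly DS3 had 63.01 CPM of EGLN3 (5.61 and 7.06 in the others), 52.39 of IGFBP1A (6.0 and 6.56) and 97.17 of P4HA1B (3.93 and 4.09). At 90% epiboly DS2 had 59.79 of ENO1A (1.78 and 2.8) and 152.23 of GAPDHS (2.67 and 5.13), and bud DS4 was highest in 5 of the 7, with 46.53 of EGLN3, and within the range of the other bud libraries for ENO1A (5.12) and GAPDHS (4.7). No test was made. CA9, a carbonic anhydrase, lay between 65.72 and 107.14 CPM in the bud libraries and at 30.35, 15.54 and 9.91 in those of the somite stages.

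A set of 9 genes named for clones differed between libraries of 1 stage. Summed, they had 5440 CPM in 75% DS2 and 155 in 75% DS4, a 35.1-fold difference, and 966 in 50% DS4 against 128 in 50% DS4b, a 7.58-fold difference. Their deviation from the stage mean had a Pearson r of -0.44 with that of replication genes over the 17 libraries (permutation p = 0.213, Spearman rho = -0.09, permutation p = 0.772, r = 0.04 without the 2 farthest), and batch took 28.1% of its variance (permutation p = 0.197).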
